A study of Mus musculus with 2 samples.

How the data were processed

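Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against H3K9me3, the trimethylated lysine of histone H3 found in heterochromatin, was carried out on midbrain dissected from mouse embryos (strain B6NCrl) at embryonic day 16.5. The labels give 1 group of 2 biological replicates, each a pool of embryos of mixed sex. Replicate 1 was sequenced as 2 technical replicates. Replicate 2 came from a pool of 37 embryos and was sequenced as 4 technical replicates. No condition was set against another, so the comparisons are between the replicates, and between the peaks and the genome.

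The authors deposited 4 peak lists, namely 1 for each replicate, 1 called on both replicates together (pooled) and 1 of replicated peaks, which per the file headers was derived from the pooled list and both replicate lists. Per the file headers the coordinates are those of mouse assembly mm10 and the technical replicates of a biological replicate were combined before peaks were called. The aligner, the peak caller and their versions are not given in the sources used here. In the deposited lists the enrichment of a peak is a fold (a ratio of ChIP over control, without a unit), and its significance is the −log10 of a p-value and the −log10 of a q-value, all from the authors' peak caller. These values describe, rank or filter peaks within a list and were not rescaled. The lowest −log10 p in the deposited lists ranged from 2.00 to 2.03, while the −log10 q went down to between 0 and 0.226, so the lists include peaks that would miss a common q threshold. A −log10 q of at least 2 was met by 40.5% of replicate 1 peaks, 31.5% of replicate 2 peaks, 38.5% of pooled peaks and 61.5% of replicated peaks. The files hold no read counts, so the depth of each library is unknown, and no interval that needs it is given.

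The replicated list was compared with the others before use. All 21388 replicated peaks had the coordinates of a pooled peak. On the main chromosomes, 16711 pooled peaks overlapped a peak of each replicate by at least 50% of either peak, and all 16711 were in the replicated list. The other 4424 replicated peaks did not meet that rule, and 14 touched no peak of either replicate list. How these entered the list is not given in the sources used here, so the main results were also computed on the 16711 peaks alone, a choice made after the data were seen.

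Peaks on chromosomes 1 to 19, X and Y were analysed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Gene positions came from GENCODE M21 on the GRCm38.p6 reference, the same assembly as mm10. A gene was marked when a peak overlapped its body or the 1 kb upstream of its start by at least 1 bp. Peaks were placed by their midpoint in promoters (1 kb either side of the start of a basic transcript), otherwise in exons, introns or intergenic sequence. Overlaps were computed with interval code written in numpy. Chance was estimated by circular-shift permutation. All peaks of a chromosome were moved along its sequenced bases by 1 random distance of at least 1 Mb, which keeps their spacing, and the count was repeated for 1000 shifts with a fixed seed. The permutation p is two-sided, and the smallest value that 1000 shifts can give is 0.0020. Peaks of 1 region move together, so the shifts take account of clustering of peaks and of genes. Overlap between replicates counted a peak as found when at least 50% of its length lay in a single peak of the other list. Correlations of log2 fold are across peaks, which are not independent replicates, and carry no p. Values as mean ± SD are over the 2 replicate lists (n = 2), each of which holds more peaks than the replicated list. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only.

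Before the data were examined, 23 gene lists were fixed. They hold Zfp zinc finger genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, imprinted genes, germline genes, 2-cell stage genes, H3K9me3 machinery, midbrain genes, neuronal genes, radial glia genes, housekeeping genes, Hox genes, muscle genes, liver genes, major urinary protein genes, Cyp2 genes, Serpin clusters, killer lectin-like receptors, Rhox genes, X-linked multicopy testis genes, blood genes, and genes of vessels, microglia and meninges. The permutation p of the lists was adjusted by the Benjamini-Hochberg method over the 23 lists, with a threshold of 0.05. The genes to name were also fixed by rule. These were the 20 protein-coding genes with the most bases under replicated peaks, the 3 genes of each list with the highest fold among those with a peak in both replicate lists, up to 5 marked genes of each list of genes used in this tissue (housekeeping, midbrain, neuronal, radial glia, H3K9me3 machinery), the 10 replicated peaks of highest fold and the 10 windows of 1 Mb with the most covered bases. A gene named outside this rule is said to have been chosen after its values were seen.

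The shift test was tested on simulated data, in which 60 of 200 random protein-coding genes were given a peak among 21135 randomly placed peaks. It found 90 of the 200 marked against 46.2 after shifts (permutation p = 0.0020), and called 0 of 20 lists without added peaks at an adjusted p of 0.05. Neither the simulated peaks nor these lists were clustered, so the rate of false calls for clustered families was not tested. With 20.0% of 68444 peaks copied into a list of random peaks, the overlap step found 20.5%, against 0.817% after shifts. The alternatives were other overlap rules, a stricter q, equal numbers of top peaks, either replicate left out (the other replicate's own list), the pooled list, the upper part of the replicated list by q, other ways to place peaks on genes, 10000 random gene lists matched on gene length, covered bases in place of peaks, and windows of 500 kb. Peaks on scaffolds outside the main chromosomes were left out of all comparisons, since their place in the chromosomes is unknown or known only in part, and are described after the report.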

Results

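H3K9me3 was mapped in the midbrain of mouse embryos at embryonic day 16.5, in 2 pools of embryos that served as biological replicates. Replicate 1 had 68795 peaks over 19.9 Mb, with a median width of 233 bp, and replicate 2 had 66335 peaks over 17.0 Mb, with a median width of 211 bp. The pooled list held 42685 peaks and the replicated list 21388, which covered 8.24 Mb with a median width of 313 bp. The authors' median fold of ChIP over control was 3.33 in replicate 1, 3.59 in replicate 2 and 3.70 in the replicated list, and the highest fold in each list was 18.6, 20.8 and 15.4. Most peaks were therefore narrow and modestly enriched. The number of reads behind them is unknown. All coordinates are on mm10.

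The first question was how far the replicates shared their peaks. Of the replicate 1 peaks, 11434 of 68444 (16.7%) were found in replicate 2, against 0.649% after circular shifts (permutation p = 0.0020, the smallest the shifts can give). Of the replicate 2 peaks, 13851 of 66000 (21%) were found in replicate 1, against 0.795% after shifts (permutation p = 0.0020). The observed shares were 25.7 and 26.4 times those after shifts, yet most peaks of either replicate had no counterpart in the other. Counting any overlap of 1 bp raised the shares to 27.7% and 29.7%, and asking for 50% of both peaks lowered them to 13.5% and 14%. At a −log10 q of at least 2 they were 13.5% and 21.1%, and for the 10000 top peaks of each list, a choice made after the data were seen, 14.5% and 17.98%. The bases covered in both replicates made up 13.1% of the bases covered in either. Sharing was highest at the most enriched peaks. Of the 10% of replicate 1 peaks with the lowest fold 11.1% were found in replicate 2, and of the 10% with the highest fold 33.2%. For replicate 2 these shares were 15.7% and 39.4%. Across the 11434 shared peaks, which are not independent, the fold in the replicates was weakly correlated (Pearson's r = 0.24 and Spearman's rho = 0.20 on the log2 scale). A fold from a single replicate therefore ranked the shared peaks poorly.

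**Figure D1:**
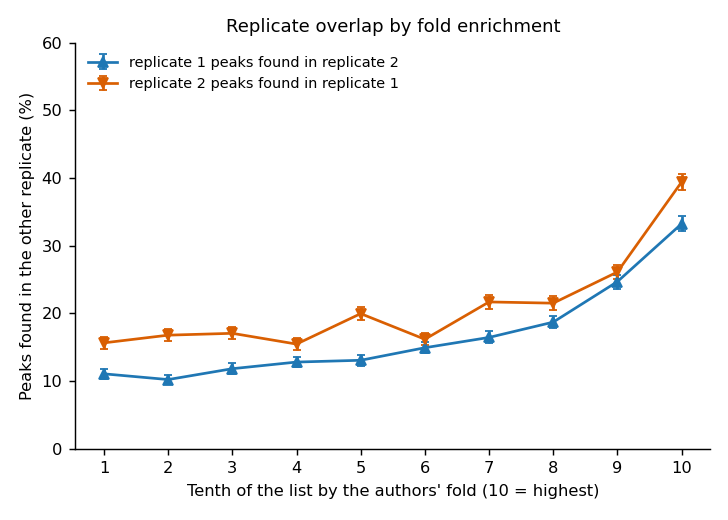
Share of peaks of each replicate found in the other (y axis, percent) by the authors' fold, in 10 classes of equal size (x axis, 10 is the highest), with exact 95% binomial intervals as bars. The share is highest in class 10, 33.2% for replicate 1 peaks and 39.4% for replicate 2 peaks.

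Replicated peaks were placed unevenly along genes. Intergenic sequence held 55.7% of them, against 49.9% after shifts (permutation p = 0.0040), and introns 32.2%, against 42.2% (permutation p = 0.0020). Promoters held 7.15%, against 4.73%, and exons 4.94%, against 3.2% (permutation p = 0.0020 for each). The exon excess was not past the threshold in the peaks of replicate 2 alone, where exons held 3.08% against 3.07% after shifts (permutation p = 0.92), nor for replicated peaks placed by any overlap, at 6.38% against 5.75% (permutation p = 0.11). With replicate 2 peaks placed by any overlap, exons held fewer than after shifts, at 3.99% against 4.84% (permutation p = 0.0020). Peaks were richer in G and C than after shifts, at 44.1% against 42.1%, and poorer in repeat-masked sequence, at 27.2% against 33.9% (permutation p = 0.0020 for each). In the peaks of replicate 2 alone the difference in GC content was not past the threshold, at 42.2% against 41.9% (permutation p = 0.11). How reads that match several places were treated is not given in the sources used here, so repeats without a peak are not read as lacking the mark. Of 21938 protein-coding genes, 2827 (12.9%) were marked in the body or the 1 kb upstream, and 366 (1.67%) had a replicated peak within 1 kb of the start.

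Of the 23 gene lists, 4 were marked more often than after shifts and 0 less often. Lists with few marked genes after shifts could not be called below. Housekeeping, major urinary protein and blood genes had 0 marked, the lowest count possible, against 2.14, 1.05 and 0.766 after shifts, and were not past the threshold. These were clustered protocadherins, with 53 of 57 genes marked against 15.8 after shifts, imprinted genes, with 34 of 45 against 9.81, Zfp zinc finger genes, with 134 of 391 against 54.1, and vomeronasal receptors, with 87 of 327 against 33.5. Each had an adjusted permutation p of 0.0115. At an unadjusted permutation p of 0.05, killer lectin-like receptors would have been added (6 of 22 against 1.72, p = 0.048, adjusted p = 0.22). The share of genes marked in the 2 replicate lists was 93.0% ± 0 (SD, n = 2) for protocadherins, 87.8% ± 4.71 for imprinted genes, 50.3% ± 3.80 for Zfp genes and 39.1% ± 0.865 for vomeronasal receptors. Each of the 4 lists was past the threshold in both replicate lists taken alone, but by a smaller ratio to shifts. In the replicated list and in the lists of replicates 1 and 2 that ratio was 3.36, 1.65 and 1.69 for protocadherins, and 3.47, 1.88 and 1.81 for imprinted genes. It was 2.48, 1.5 and 1.42 for Zfp genes, and 2.60, 1.45 and 1.59 for vomeronasal receptors. In the list of replicate 1 alone 3 more lists passed, with germline genes (adjusted permutation p = 0.046) and Hox genes (adjusted permutation p = 0.015) above their shifts, and housekeeping genes below, with 0 of 30 marked against 6.47 (adjusted permutation p = 0.0115). Where the peak had to lie within 1 kb of the start, the lists past the threshold were 3, and they differed. Protocadherins (50 of 57 against 0.646), imprinted genes (20 of 45 against 0.983) and germline genes (7 of 40 against 0.619) each had an adjusted permutation p of 0.015. Zfp starts (7 of 391 against 8.59, adjusted permutation p = 1) and vomeronasal starts (22 of 327 against 8.97, adjusted permutation p = 0.43) were not past it.

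**Figure D2:**
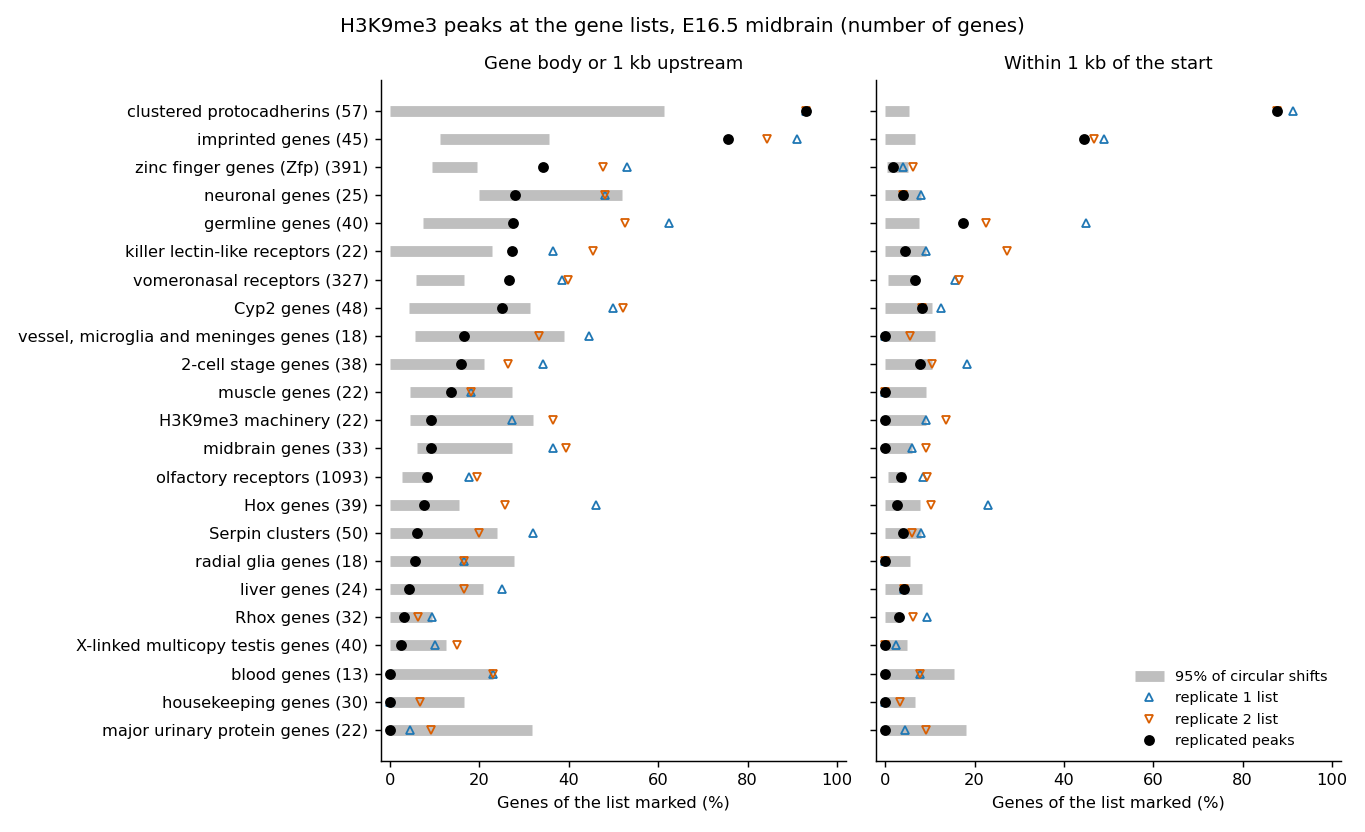
Percent of the genes of each list (x axis, number of genes in brackets) with an H3K9me3 peak in the body or 1 kb upstream (left) or within 1 kb of the start (right). Filled circles are replicated peaks, grey bars the central 95% of circular shifts of those same peaks, and triangles the longer lists of each replicate, which the bars do not apply to. Clustered protocadherins (93.0% on the left, 87.7% on the right) and imprinted genes (75.6% and 44.4%) lie beyond the bars in both panels.

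The clustered protocadherins, cell-surface adhesion proteins of which each neuron uses a small subset, formed the most heavily marked stretch of the genome. Between 36930184 and 37841873 on chromosome 18 the replicated list held 384 peaks over 234 kb. Replicate 1 had 492 peaks over 260 kb there and replicate 2 had 530 over 223 kb. All 20 protein-coding genes with the most covered bases lay in this stretch. Besides 3 gene models that span several clusters (Gm42416, Gm37013 and Gm37388), these were genes of the alpha cluster (Pcdha1 to Pcdha5) and of the gamma cluster (Pcdhga1 to Pcdhga8, Pcdhgb1, Pcdhgb2, Pcdhgb4 and Pcdhgb5). Gene bodies in the alpha and gamma clusters overlap, because each variable first exon is spliced to shared exons, so their values are not separate. In Pcdhga1 (37661793 to 37841873) replicated peaks covered 84880 bp, or 46.9% of the searched sequence, and the replicate lists 79599 ± 11416 bp (SD, n = 2). In Pcdha1 (36930184 to 37187661) they covered 54986 bp, or 21.3%, and the replicate lists 55838 ± 3968 bp. The first exons are specific to a gene. A replicated peak lay on the first exon of 13 of 14 alpha genes, 22 of 22 beta genes and 18 of 21 gamma genes, and each replicate's own list also reached 53 of the 57. Peaks were dense in this stretch, and how many first exons they would reach if placed at random within it was not computed. The 4 first exons without a replicated peak belonged to Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, named here after their values were seen. They are genes of the C type, which, unlike the other clustered protocadherins, are not chosen at random by each neuron. Of the C-type genes only Pcdhac1 had a replicated peak on its first exon.

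**Figure D3:**
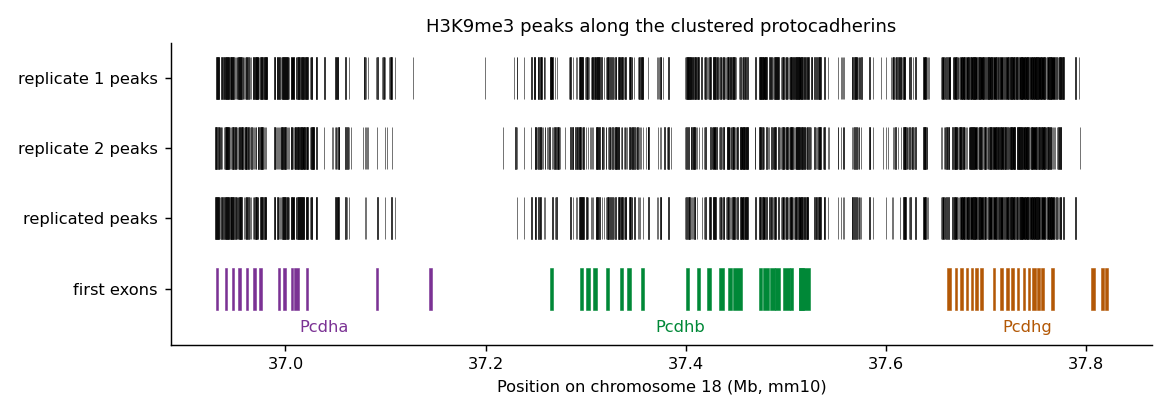
Map of the clustered protocadherins on chromosome 18 (x axis, Mb, mm10), with the peaks of each replicate, the replicated peaks and the first exons of the Pcdha, Pcdhb and Pcdhg genes. Each of the 3 lists has a peak on 53 of the 57 first exons, and the first exons of Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5 have none. First exons were not compared with the sequence between them.

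Zinc finger genes of the Zfp family, many of which encode DNA-binding repressors with arrays of fingers in the last exon, were marked at that exon and not at their start. Of the 389 with several exons, 97 (24.9%) had a replicated peak over the last exon, against 2.73% after shifts (permutation p = 0.0020), whereas 7 (1.80%) had one within 1 kb of the start, against 2.20% (permutation p = 0.93). The last exons had a median length of 2501 bp, close to the 2001 bp searched around the start. Only the last exon was marked in 92 genes and only the start in 2 (exact McNemar p = 4.5e-25). The McNemar test counts each gene as independent, which neighbouring genes of a cluster are not, so its p overstates the evidence. In the replicate lists alone the last exon was marked in 34.7% and 30.1% of genes. In Zfp981 and Zfp982, 65.7% and 73.3% of the 50-mers of the last exon also lie elsewhere in the genome, and in Zfp810 0%. The highest fold was seen in Zfp981 on chromosome 4 (146502027 to 146539395), with 21 peaks and a fold of up to 10.3. That peak lies in an intron. The order of the genes depended on the replicate, since in Zfp981 the fold was 7.06 in replicate 1 and 11.8 in replicate 2, and in Zfp810 it was 11.2 and 7.57. In Zfp982, also on chromosome 4 (147492417 to 147513486), the fold reached 9.36, and in Zfp810 on chromosome 9 (22276748 to 22307648) it reached 9.76. Replicated peaks covered 12853 bp of Zfp981, and the replicate lists 13725 ± 1660 bp (SD, n = 2).

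Imprinted genes, expressed from the allele of 1 parent, had 34 of 45 members marked and 20 of 45 marked at the start. The highest fold among the genes of this list, which does not hold Klf14, was 7.24, at Nnat on chromosome 2 (157560078 to 157562522), which lies within an intron of Blcap (157556362 to 157571274), so both genes share the peak. The fold at Nnat was 5.0 in replicate 1, where Impact (6.47) and other genes of the list were higher, and 8.52 in replicate 2. Nnat encodes a small membrane protein of the developing brain. Its replicated peaks covered 1775 bp, or 51.5% of the searched sequence, and the replicate lists 1696 ± 636 bp (SD, n = 2). The third gene by fold was Mest on chromosome 6 (30723547 to 30748465), at 5.95. Starts marked by replicated peaks, picked out after their values were seen, included those of Peg3, Kcnq1ot1, Airn, Plagl1, Peg10, Impact, Gnas, Meg3 and Snurf, at several of which the methylated regions that govern imprinting are known to lie.

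Germline genes, used in the formation of eggs and sperm, were not past the threshold by their bodies (11 of 40 against 6.67 after shifts, adjusted permutation p = 0.38) but were by their starts. The replicate lists marked the start of 33.8% ± 15.9 of them (SD, n = 2). The 7 genes with a marked start, named after their values were seen, were Ddx4, Dazl, Mael, Sycp1, Meioc, Taf7l and Fkbp6, the last of which also stands on the imprinted list. Ddx4, an RNA helicase of germ cells, on chromosome 13 (112598333 to 112652475), had a fold of 7.54 in the replicated list, 4.16 in replicate 1 and 11.6 in replicate 2. Taf7l on chromosome X (134460118 to 134476490), a germ cell form of a general transcription factor subunit, had 5.52, 3.67 and 8.40. Tdrd9 on chromosome 12 (111971559 to 112068854) reached 4.71, in its body only.

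Vomeronasal receptors, the pheromone receptors of the vomeronasal organ, had 87 of 327 genes marked, mostly in their bodies. The highest fold in the replicated list was 6.33, at Vmn1r70 on chromosome 7 (10631532 to 10636530), with 6 peaks over 39.8% of the searched sequence. The order depended on the list. Vmn1r70 had 5.19 in replicate 1, where Vmn2r106 reached 6.11. In replicate 2 it had 6.09, where Vmn2r105, named after its values were seen, reached 6.80. Vmn2r61, on chromosome 7 (42260053 to 42300755), and Vmn2r106, on chromosome 17 (20266767 to 20285553), both reached 6.13. Olfactory receptors, which detect odours in the nose, had 91 of 1093 genes marked against 55.3 after shifts (adjusted permutation p = 0.36), and the highest folds were 5.93 at Olfr943, 5.65 at Olfr1349 and 5.52 at Olfr398. Against random genes of matched length, which take no account of clustering, the olfactory count was past the threshold (91 against 42.0, adjusted permutation p = 0.00092), as were those of Cyp2 genes and killer lectin-like receptors.

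The lists of genes that embryonic midbrain or most cells use were marked in numbers not distinguishable from those after shifts. The share marked ran from 0% for housekeeping genes to 28% for neuronal genes, against 12.9% of all protein-coding genes. Housekeeping genes had 0 of 30 marked, against 2.14 after shifts (adjusted permutation p = 0.54). A lower count is not possible, so this test could not show a depletion of that list. Midbrain genes had 3 of 33, against 5.37, and these were Lmx1a, Tcf7l2 and Tfap2b, transcription factors of the developing midbrain or its borders, each with a fold of at most 4.11. Neuronal genes had 7 of 25, against 8.70, led by the synaptic adhesion gene Nrxn1 (chromosome 17, 90033631 to 91093071) at a fold of 6.58, with the peak at its start, then Syt1 at 5.32, Nefm at 4.35, Snap25 at 4.11 and Ank2 at 3.79. Radial glia genes, which mark the neural stem cells of the embryo, had 1 of 18, the growth factor gene Ptn at 3.30. The H3K9me3 machinery had 2 of 22, Atf7ip, which encodes a partner of the methyltransferase SETDB1, at 4.90 and the demethylase gene Kdm4c at 3.10. The adjusted permutation p of these last 4 lists lay between 0.64 and 1.

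Lists of other tissues and families were also not past the threshold by gene body. Marked were 6 of 38 genes of the 2-cell stage (Pramel5 at 5.28, with Pramef12 and Pramef20 at 4.92 but higher than Pramel5 in replicate 1), 12 of 48 Cyp2 genes (5.46, Cyp2b13, then Cyp2c38 and Cyp2c39), 3 of 39 Hox genes (4.57, Hoxa11, then Hoxb3 and Hoxc11), 3 of 50 Serpin genes (4.92, Serpinb6d, then Serpina10 and Serpinb9e) and 6 of 22 killer lectin-like receptors (5.46, Klra17, then Klra7 and Klra1). Of genes used by other cell types, 3 of 22 muscle genes were marked (Ttn, Ryr1 and Neb), 1 of 24 liver genes (Cyp3a11), 0 of 13 blood genes and 3 of 18 genes of vessels, microglia and meninges (Tek, Pdgfrb and Flt1). Ttn, the giant sarcomere protein, had 38 replicated peaks over 21480 bp, or 7.68% of a long gene (13.7% in Cyp3a11), and 25234 ± 10506 bp in the replicate lists (SD, n = 2). Among X-linked or tandem families, 1 of 32 Rhox genes (Rhox13), 1 of 40 X-linked multicopy testis genes (Mageb18) and 0 of 22 major urinary protein genes were marked. The sample is whole tissue, so no peak can be assigned to a cell type.

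Chromosomes differed widely in the density of replicated peaks. Chromosome 7 had 23.5 peaks per Mb of sequenced bases, chromosome 17 had 15.2 and chromosome 4 had 12.4, while the autosomes together had 8.65. Chromosome 7 held 15.8% of the replicated peaks and 5.36% of the sequence. Its density was 3.04 times that of the other autosomes in the replicated list and 2.12 ± 0.036 times in the replicate lists (SD, n = 2). Chromosome X had 2.43 peaks per Mb and Y had 0.091. How much of Y short reads can be placed on was not analysed here, so its density is not read as a lack of H3K9me3. The density on X was 0.28 times that of the autosomes in the replicated list, but 0.65 times in the list of replicate 1 and 0.90 times in the list of replicate 2, so the size of the deficit on X depended on the list. No permutation test was run on these densities.

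The densest windows of 1 Mb mostly held clusters of related genes. After the protocadherin window on chromosome 18 (37000001 to 38000000, 202 kb covered), the next was on chromosome 4 (144000001 to 145000000, 114 kb), with Oog2, Oog3, Pramel and Aadacl genes. The third, on chromosome 12 (114000001 to 115000000, 110 kb), held 49 V segments of the immunoglobulin heavy chain and 0 protein-coding genes. On chromosome 7, windows starting at 17000001 (103 kb) and 18000001 (74.0 kb) held 2 and 11 Psg genes and 4 and 2 Ceacam genes, whose products include the glycoproteins of placenta and pregnancy. The window at 33000001 (91.2 kb) held 12 Scgb genes of the secretoglobin family, the window at 12000001 (88.2 kb) held 12 vomeronasal receptors and 7 Zfp genes, and the window at 10000001 (86.4 kb) held 9 vomeronasal receptors and Zscan4b. The remaining windows lay on chromosome 13 (61000001 to 62000000, 96.9 kb), with 8 cathepsin genes such as Ctsj and Cts6, several of which are used in the placenta, and on chromosome 10 (82000001 to 83000000, 82.5 kb), with Zfp873 and Zfp938. Coverage in the replicate lists was 210 ± 21.7 kb in the protocadherin window and 149 ± 7.91 kb in the immunoglobulin window (SD, n = 2). The median window of the genome had 1.29 kb covered, 327 of 2737 windows had 0, and the top 10 windows held 13% of all covered bases. Of these 10 windows, 6 were also among the top 10 of replicate 2's own list, and all 10 were among those of replicate 1.

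The replicated peak of highest fold lay over Klf14, an imprinted single-exon gene of a transcription factor, on chromosome 6 (30956258 to 30959241), at 15.4 in the replicated list, 18.6 in replicate 1 and 7.89 in replicate 2. Of the 10 peaks of highest fold, 5 lay on scaffolds outside the main chromosomes. The others included a promoter peak of 1216 bp shared by Tmem267 and 3110070M22Rik on chromosome 13 (119488151 to 119489366, 11.7), a peak in Pcdhgb6 on chromosome 18 (37744271 to 37744690, 10.97), a peak in an intron of Zfp981 (146534896 to 146535589, 10.3) and a promoter peak of Gm21887 near the end of chromosome X (170009020 to 170010014, 10.2). In the replicated list the −log10 p was 170 at the chromosome 13 peak and 144 at the chromosome X peak, against 52.0 at Klf14, where the fold was higher. What sets these 2 peaks apart was not tested. At 3 of the 5 on the main chromosomes the fold in replicate 2 was over 2 times that in replicate 1, with 20.8 against 4.59 on chromosome 13, 17.8 against 6.23 on chromosome X and 11.8 against 4.24 in Zfp981.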

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

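The tests of GC content and of replicate scatter at peaks stronger in replicate 2, and that of X copies with the fold doubled, were chosen after the result was seen, each in place of an earlier form that had pooled peaks of unlike GC content, counted the named peaks among those they were compared with, or ranked peaks by a fold that X copies can lower. A signal also appeared in sequence that the comparisons did not use. The replicated list held 253 peaks on 25 scaffolds outside the main chromosomes, which covered 194312 bp. Replicate 1 had 351 and replicate 2 had 335 peaks on scaffolds. The median fold of the 253 peaks was 3.79, against 3.70 on the main chromosomes, and 5 of the 10 replicated peaks of highest fold were among them.

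Last exons of Zfp genes carried peaks in 97 of 389 genes (24.9%, exact 95% interval 20.7% to 29.5%). Other protein-coding genes with last exons of similar length and GC content had a peak there in 2.84% (50 of 1762, interval 2.11% to 3.72%), which argues against exon length and base composition as the cause. Of the marked last exons, 78.4% (interval 68.8% to 86.1%) had under 10% of their 50-mers elsewhere in the genome, and 71.5% of the unmarked ones did, which argues against reads shared between near-identical paralogs as the cause for most of these exons. It does not cover Zfp981 and Zfp982, at 65.7% and 73.3% of 50-mers elsewhere. The design has no second group, so no biological explanation was tested. Whether the peaks over the last exon lie on its finger-coding part was not examined, so that remains a hypothesis.

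Chromosome X carried few replicated peaks, at 0.281 times the density of the autosomes (exact 95% Poisson interval 0.254 to 0.310, counting error only). The ratio was 0.397 in the pooled list, and 0.653 and 0.904 in the lists of replicates 1 and 2 alone. A mixed-sex pool holds fewer copies of X than of an autosome, which lowers the power for weak peaks. Among the strongest 10% of peaks the ratio was 0.19 (interval 0.13 to 0.28), but fewer copies can also lower the fold of X peaks and so keep them out of that class. With the fold on X doubled, the most that 1 copy against 2 can take away, the ratio at that fold was 2.68. A pool of mixed sex loses less than that, and a smaller factor was not tried. The doubling carried 393 of the 397 X peaks past that fold, so a high ratio was fixed in advance and decides nothing. Fewer copies of X stay open as a cause, since neither of these ratios can tell. In the replicated list the ratio was 0.377 (interval 0.337 to 0.420) for sequence outside repeat-masked bases. It was 0.297 (interval 0.262 to 0.335) outside the 1 Mb windows with genes of clustered families. These values argue against repeats and against those families as the whole cause of the deficit in that list. A part due to repeats is not excluded, since the interval outside repeats lies above that of all replicated peaks. No biological explanation was tested.

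Peaks much stronger in replicate 2 than in replicate 1 were seen on chromosome 13 at Tmem267, on chromosome X at Gm21887 and in Zfp981, with log2 ratios of 2.18, 1.51 and 1.48. Other peaks within 3 percentage points of their GC content had a median log2 ratio of −0.051, 0.254 and 0.126, and a 95th percentile of 0.99, 1.30 and 0.86. The named peaks were picked for a log2 ratio over 1. On chromosome 13 and in Zfp981 a ratio above the 95th percentile was therefore fixed by the choice of peaks. On X the comparison rests on 15 peaks. GC content thus stays open at all 3. Among 103 other strong peaks (−log10 p of at least 20), 0.971% (1 peak, exact 95% interval 0.025% to 5.29%) differed as much, so scatter between replicates was not excluded. That peak overlapped Asmt on chromosome X (170676192 to 170678052), with a fold of 4.89 in replicate 1 and 14.4 in replicate 2. It lies near the Gm21887 peak (170009020 to 170010014), and both are rich in G and C, at 66.1% and 74%. The Asmt peak may therefore not be a separate case. No biological explanation was tested.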

How the results depend on the processing

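Among the alternatives to the main results, 74 of 96 kept the direction and the side of the threshold, or moved by less than the spread allowed. Those on the 16711 replicated peaks in both replicate lists and on the 10000 top peaks were chosen after the data were seen. The overlap between replicates exceeded its shifts under every rule tried. The correlation of fold was 0.19 with an overlap of 1 bp and 0.28 at a −log10 q of at least 2. The exon share was past the threshold in the main setting, but not for any overlap (6.38%), and it ranged from 3.08% to 4.10% with either replicate left out. Either replicate left out gave between 4 and 6 gene lists above and between 0 and 1 below their shifts, and 7 lists were above random lists matched on length, which ignore clustering. At the start, the ratio of marked Zfp genes to shifts was 0.815, which was not distinguishable from chance. The density on X over the autosomes ranged from 0.65 to 0.90 with either replicate left out, and was 0.397 in the pooled list, 0.207 in the upper part by q, 0.269 by bases and 0.292 for peaks in both lists. For chromosome 7 that range was 2.10 to 2.15, and the ratio was 2.71 in the pooled list, 3.15 in the upper part by q, 3.11 by bases and 3.14 for peaks in both lists. For chromosome 17 the range was 1.54 to 1.67. For chromosome 4 it was 1.15 to 1.28, with 1.32 pooled, 1.62 by q and 1.58 by bases. Of the 10 densest windows, 6 to 10 stayed among the top 10 with either replicate left out. Except where stated, the cause was not tested. The replicate lists are longer and hold more weak peaks, and the unknown depth limits what can be said of unmarked genes.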

Other observations

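V segments of the antigen receptors were examined after the window on chromosome 12 had been seen, and the test by the intervals of the shares was chosen after the result was seen, in place of one on the T cell receptor segments against shifts alone that had left the question open. Of 113 V segments of the immunoglobulin heavy chain, 36 (31.9%) were marked in the body or the 1 kb upstream, against 1.12 after shifts (permutation p = 0.00020, the smallest that 10000 shifts can give), and 41.6% ± 6.26 (SD, n = 2) in the replicate lists. The heavy chain locus was picked for its many covered bases in the same replicated peaks, so this p is no independent evidence. Of 100 V segments of the kappa light chain, 0 were marked in the replicated list and 4 and 2 in the lists of replicates 1 and 2. If V segments carried the mark as a class, those of the T cell receptor would be marked too. They were marked in 2 of 144, against 1.31 after shifts (permutation p = 0.71). The exact 95% upper bound of the share marked was 4.93% for T cell receptor segments and 3.62% for kappa segments, against a lower bound of 23.4% for the heavy chain, which argues against a property of all V segments. The intervals cover counting error only, neighbouring segments are not independent, and the heavy chain was picked for its peaks.

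Other gene families were scanned after the fixed lists had been tested, with families defined by a shared start of the gene symbol and at least 10 protein-coding members. Genes of the 12 fixed lists that were defined by a symbol pattern, and symbols of gene models such as Gm, were left out first. Of 264 families, 0 passed an adjusted permutation p of 0.05 in either direction, and the lowest adjusted permutation p was 0.52. At an unadjusted permutation p of 0.05, 4 families were above and 10 below their shifts, in total about as many as chance alone gives where every family can pass. Families with few marked genes after shifts could not pass below, such as Fzd genes (0 of 10 against 0.658, permutation p = 0.99). Those with the lowest p among the families below were Wdr genes (4 of 64 against 12.0, permutation p = 0.0046) and Tmem genes (18 of 242 against 29.8, permutation p = 0.0096). Those above were Nlrp genes (10 of 17 marked against 3.87 after shifts, permutation p = 0.0048), Tas genes, among them the bitter taste receptors (5 of 38 against 0.643, permutation p = 0.0090), Ceacam genes (8 of 15 against 1.87, permutation p = 0.024) and Scgb genes (9 of 34 against 1.65, permutation p = 0.033). Skint genes (8 of 11 against 3.51, permutation p = 0.051) and Psg genes (6 of 13 against 1.60, permutation p = 0.13) were not past 0.05. A family in 1 or a few clusters moves as a block under the shifts, so the dense windows that hold such families are not by themselves evidence for a family.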
